A study of Mus musculus with 9 samples.

How the data were processed

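Monocytes were sorted from the spleens of C57BL/6 mice, per the labels' protocols, at 40000 to 50000 cells per library. Libraries were made from 10 ng of total RNA with the SMARTer Ultra Low kit and 12 to 15 PCR cycles and sequenced as paired reads of 150 bases. The 9 libraries form 3 groups of 3 (WT Ly6Chi, WT Ly6Clo and KO Ly6Clo), taken with their replicate numbers from the titles. KO denotes homozygous loss of the +37 element of Cebpa. No Ly6Chi library of KO mice was analysed here.

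Each library has 1 table of 55487 gene IDs. The deposited counts are whole numbers of reads per gene, not normalized, per the file headers. The tables also hold CPM, FPKM and TPM, deposited by the authors beside the counts, and these equal the values recomputed from the count and length columns (largest difference 6e-11). The CPM, FPKM and TPM columns as deposited were used in no test. The submitters' processing notes name STAR 2.5.1a, Subread featureCounts 1.4.6-p5, Salmon 0.8.2, bcl2fastq, edgeR and limma and the build GRCm38 (mm10), without giving roles. How reads of several genes were assigned, and whether strand was used, is not given in the sources used here. Reads of overlapping genes, of a gene and its antisense partner, and of near-identical copies (Ly6c1 and Ly6c2, Chil3 and Chil4, Hba-a1 and Hba-a2, the Ly6a family, Hspa1a and Hspa1b) are therefore less certain. Symbols came from the GENCODE M21 annotation of the same build for 55141 IDs (99.38%). Of the 55227 IDs found there, 54870 (99.35%) had identical coordinates in the tables. IDs without symbol took at most 0.063% of the counts of a library. Coordinates are those of the tables, counted from 1.

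Depth ran from 48.1 to 173.7 in units of 1000000 counts per library, so 3 counts equal 0.0199 to 0.0626 CPM. Intervals and floors cover counting error only, because PCR copies cannot be told from molecules without molecular identifiers. A fold against a group whose libraries were all at 0 is given as a bound against the mean CPM of 3 counts in each library of that group, and against a group with 1 to 3 counts as a 95% interval from the counts. Replicates were compared before use. The chi-square statistic per gene between libraries of 1 group ran from 56.4 to 547, so no pair looked like 1 library deposited again.

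Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10, 18341 genes kept), TMM scaling, a model with 1 term per group over all 9 libraries, and the quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment. A gene is called when the adjusted p is under 0.05. The common dispersion was 0.448. All 9 libraries share 1 estimate of the spread because the groups are few and small. Library levels are CPM on TMM-scaled library sizes computed from the counts. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic. The comparisons were KO Ly6Clo against WT Ly6Clo, WT Ly6Clo against WT Ly6Chi and KO Ly6Clo against WT Ly6Chi. Design, gene lists, rule for named genes and the alternatives given below were fixed before the data were examined.

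The 25 gene lists hold 306 genes, 305 of them matched (Ahsp was not): C/EBP family, Ly6Chi and Ly6Clo monocyte genes, primary granule and progenitor genes, neutrophil genes, monocyte transcription factors, growth factor and cytokine receptors, chemokine receptors and adhesion, MHC class II, Fc receptors with complement and phagocytosis, lipid handling, inflammatory cytokines, interferon response, cell cycle, immediate early and heat shock, markers of conventional and plasmacytoid dendritic cells, red pulp macrophages, B, T and NK cells, eosinophils with basophils and mast cells, erythroid cells and platelets with megakaryocytes, and sex-linked genes. Lists were tested with camera of limma 3.58.1 on log-CPM, with a preset correlation of 0.01, adjusted over the lists of a comparison. Members were counted as adjusted over all genes and as adjusted over the list alone. Subset scores are the mean of log2(CPM + 1) over a list, compared by a two-sided exact permutation test.

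Named genes follow this rule in each comparison. Cebpa, Cebpb, Ly6c2, Ccr2, Nr4a1, Cx3cr1, Treml4 and Itgal are always named. So are the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with at least 5 CPM in the higher group and no overlap between groups, without predicted genes of Gm or Rik symbols, pseudogenes, receptor segments and IDs without symbol. Per list, up to 4 called members with the smallest adjusted p are named, or up to 2 of the highest level where none was called. Results for some genes that the rule names are not reported here.

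The alternatives were RLE scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 2 groups compared, the replicate number as a block, a term for the 2 runs of library numbers (5 and 4 libraries), each library left out in turn and an absolute log2 fold change of at least 1. For the lists they were an estimated correlation and fry, for the scores a pseudocount of 0.1 CPM and tested genes alone, for neighbors of Cebpa a window of 250 kb in place of 1 Mb. A term for the libraries numbered 1, a fit without them and the C/EBP family list without Cebpa were added after the data were seen. Overlaps between comparisons with shared libraries were set beside 20 simulations of unchanged groups.

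The tests were checked on simulated counts for 18341 genes, in a single draw per comparison from the means, library sizes and edgeR dispersions of these data. Changed were 200 genes of at least 5 CPM and, by a fold of 4, the lipid handling list. Recovery is given for the former, and the share of calls on unchanged genes depends on how many genes were changed. Simulating KO Ly6Clo against WT Ly6Clo, edgeR recovered 7.46% of genes changed by a fold of 2, 70.1% at a fold of 4 and 87.9% at a fold of 8, with 4.72% of its calls on unchanged genes. DESeq2 recovered 50.7%, 94% and 93.9%, with 33.6% of its calls on unchanged genes, and limma-voom 11.9%, 70.1% and 86.4% with 3.91%.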

Results

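RNA was sequenced from sorted splenic monocytes of C57BL/6 mice in 3 groups of 3 libraries. Ly6Chi monocytes, the classical subset, and Ly6Clo monocytes, the nonclassical subset, came from wild-type (WT) mice. Ly6Clo monocytes also came from mice homozygous for a deletion of the +37 element of Cebpa, here called KO. Cebpa encodes C/EBP-alpha, a transcription factor of the granulocyte and monocyte lineages. In units of 1000000 counts, the gene totals were 49.6, 48.1 and 50.5 in WT Ly6Chi replicates 1 to 3, 54.4, 173.7 and 53.0 in WT Ly6Clo and 60.5, 149.8 and 54.6 in KO Ly6Clo. Levels below are CPM on TMM-scaled library sizes, as mean ± SD with n = 3 libraries, and fold changes are log2 values with their standard error (SE). The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries, which may be technical. WT Ly6Chi replicate 3 is an exception, set apart by its sex-linked genes as given below.

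Cebpa (ENSMUSG00000034957, chromosome 7, 35119293 to 35121928 in GRCm38) was lowest in the KO group. Its level was 31.5, 51.3 and 51.6 CPM in the WT Ly6Chi libraries, 18.2, 17.7 and 19.2 CPM in WT Ly6Clo, and 4.04, 2.89 and 2.74 CPM in KO Ly6Clo. KO Ly6Clo monocytes held 3.22 ± 0.709 CPM against 18.3 ± 0.768 CPM in WT Ly6Clo (log2 fold change -2.51, SE 0.27, edgeR adjusted p = 0.015). The labels do not give the bounds of the deleted element, so whether it holds counted bases of Cebpa was not tested. An antisense gene, Gm45091, overlaps the start of Cebpa and was at 0 CPM in KO and 0.237 ± 0.0816 CPM in WT Ly6Clo. Within the WT, Cebpa was lower in Ly6Clo than in Ly6Chi monocytes, at 44.8 ± 11.5 CPM (log2 fold change -1.29, SE 0.26, edgeR adjusted p = 0.032). That call was kept in 11 of 19 alternatives (adjusted p from 8.3e-05 to 0.13), and by edgeR was lost without WT Ly6Chi replicate 2 (adjusted p = 0.13) or 3 (0.12), WT Ly6Clo replicate 1 (0.12), 2 (0.12) or 3 (0.11), or KO replicate 2 (0.051). The related factor Cebpb stood at 798 ± 90.6 CPM in WT Ly6Chi, 1670 ± 692 in WT Ly6Clo and 1190 ± 198 in KO Ly6Clo, and passed the edgeR test in none of the 3 comparisons (adjusted p = 0.071, 0.95 and 0.33 for WT Ly6Clo against WT Ly6Chi, KO against WT Ly6Clo and KO Ly6Clo against WT Ly6Chi). The log2 fold change of Cebpa between KO and WT Ly6Clo lay between -2.71 and -2.41 when single libraries were left out. Its edgeR adjusted p exceeded 0.05 without WT Ly6Chi replicate 3 (0.055), WT Ly6Clo replicate 1 (0.073), 2 (0.07) or 3 (0.079), and KO replicate 2 (0.075) or 3 (0.064). It also did with the replicate block, a fit on all 9 libraries (0.056), and in a fit of the 2 groups alone (0.13). The call between KO and WT Ly6Clo was kept in 10 of 19 alternatives.

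**Figure D1:**
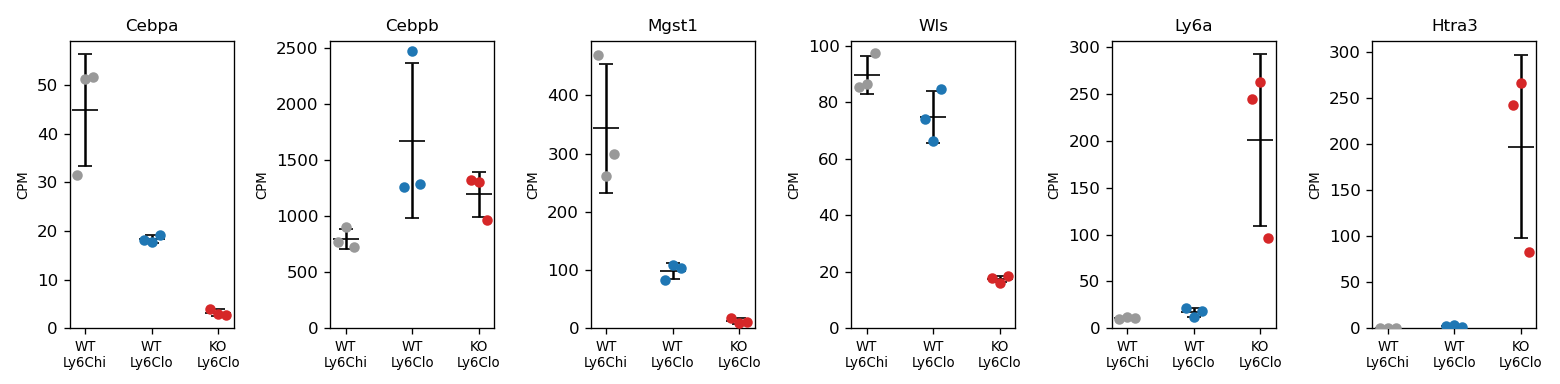
Level of 6 genes in each library (points, CPM on TMM-scaled library sizes), with the mean (dash) and SD (bars) of the 3 libraries of each group. Cebpa fell to 3.22 CPM in KO Ly6Clo, and the 3 KO libraries lay apart from the 3 WT Ly6Clo libraries for Mgst1, Wls, Ly6a and Htra3.

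The first comparison asked what the deletion changed within Ly6Clo monocytes. Besides Cebpa, 10 genes were lower in KO Ly6Clo. Plcb1, a phospholipase C, fell from 7.09 ± 4.42 to 0.0129 ± 0.0113 CPM (log2 fold change -8.76, SE 0.86). Hnmt, which methylates histamine, fell from 8.54 ± 2.61 to 0.429 ± 0.0336 CPM. Mgst1 (chromosome 6, 138140316 to 138156755), a microsomal glutathione transferase and a member of the Ly6Chi list, fell from 99 ± 13.4 to 12.5 ± 4.78 CPM (log2 fold change -2.98, SE 0.33). Abca9, an ABC transporter, fell from 73.9 ± 21 to 7.78 ± 2.11 CPM, and Stxbp6, a syntaxin-binding protein, from 11.9 ± 4.08 to 1.08 ± 0.559 CPM. Wls (chromosome 3, 159839672 to 159938664), which carries Wnt proteins to the cell surface, fell from 74.9 ± 9.25 to 17.5 ± 1.15 CPM (log2 fold change -2.10, SE 0.16, edgeR adjusted p = 0.0071). Cd40, a costimulatory receptor, fell from 25.3 ± 3.51 to 7.41 ± 1.35 CPM and Vill from 80.5 ± 8.9 to 24.3 ± 3.5 CPM. The other 2 lower genes were named after their values were seen, since both fall outside the rule for named genes. Gspt2, a translation termination factor, had 0 counts in the KO libraries and 650 in WT Ly6Clo, and Gm19951, a long noncoding RNA, fell from 161 ± 46.5 to 22.9 ± 5.91 CPM.

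Only 2 genes rose in KO Ly6Clo monocytes by this test. Ly6a, which encodes the surface antigen Sca-1, went from 17.2 ± 4.87 to 201 ± 91.4 CPM (log2 fold change 3.54, SE 0.40, edgeR adjusted p = 0.018). Htra3, a secreted serine protease, went from 2.49 ± 0.823 to 197 ± 99.4 CPM (log2 fold change 6.30, SE 0.80, edgeR adjusted p = 0.039). Ly6a lies on chromosome 15 (74994877 to 74998031) and belongs to a family of similar genes, so the assignment of its reads is less certain. Htra3 lies on chromosome 5 (35652023 to 35679782). Together 13 of 18341 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 higher and 11 lower, and 12 of the 13 were protein-coding. In all 13 the libraries of the groups did not overlap, which chance gives for 10% of genes at this size. Unadjusted p lay under 0.05 for 1130 genes, against 917 by chance. The count depended on the libraries: it was 5 without WT Ly6Chi replicate 3, 8, 5 and 2 without WT Ly6Clo replicates 1, 2 and 3, and 21 without KO replicate 1. It was 277 by DESeq2 (146 higher and 131 lower) and 16 by limma-voom (5 higher and 11 lower). It was 0 by edgeR in a fit of the 6 libraries alone, where 859 genes had an unadjusted p under 0.05. Wls passed edgeR's test whichever library was left out, Hnmt (adjusted p = 0.055) and Abca9 (0.059) missed it without WT Ly6Clo replicate 3, and Plcb1 (0.06) without KO replicate 2. Of the 9 libraries, Mgst1 and Ly6a missed it without 5, Vill and Htra3 without 6, Stxbp6 without 8 and Cd40 without 9, with edgeR adjusted p between 0.053 and 0.22.

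Of the genes of the sort and the subset, none of those named here passed the edgeR test between KO and WT Ly6Clo monocytes. Ly6c2, which encodes the Ly6C antigen of the sort, was at 2.94 ± 0.855 CPM in KO and 3.93 ± 1.58 in WT Ly6Clo, against 946 ± 104 in WT Ly6Chi. The chemokine receptor Ccr2 was at 140 ± 44.9 and 92.6 ± 8.32 CPM, against 1160 ± 301 in WT Ly6Chi. Nr4a1, a nuclear receptor on which Ly6Clo monocytes depend, was at 4500 ± 2500 CPM in KO and 6380 ± 4400 in WT. Cx3cr1, the fractalkine receptor, was at 382 ± 80.4 and 507 ± 112 CPM, Treml4 at 1200 ± 22.3 and 1650 ± 201, and the integrin Itgal at 1860 ± 512 and 2170 ± 198. Of the 18 genes of the Ly6Clo list, 17 had a negative fold change, the exception being the Fc receptor Fcgr4, and 0 were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05. The count adjusted over the list alone was 0 too (camera adjusted p = 0.18). Of the 16 genes of the Ly6Chi list 1 was lower (Mgst1), and 3 were lower when adjusted over the list alone (camera adjusted p = 0.19). As a mean of log2(CPM + 1), the Ly6Chi list scored 3.60 ± 0.24 in KO, 4.01 ± 0.07 in WT Ly6Clo and 8.67 ± 0.34 in WT Ly6Chi libraries. The Ly6Clo list scored 9.46 ± 0.09, 9.69 ± 0.03 and 7.03 ± 0.94. Each pair of groups was fully apart on both scores, with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow.

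**Figure D2:**
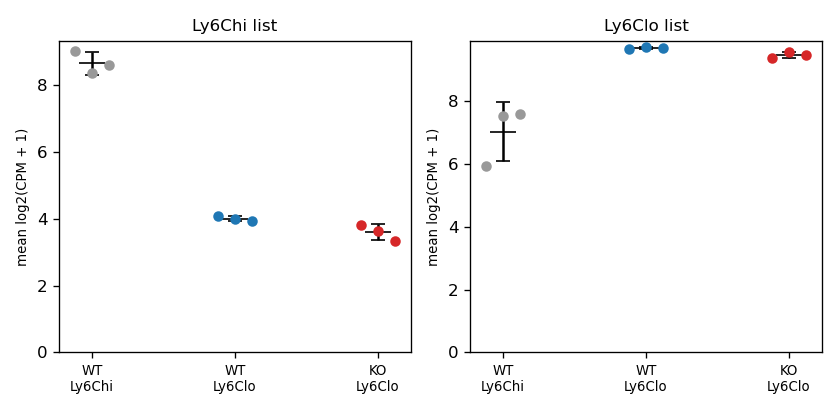
Mean log2(CPM + 1) of the genes of the Ly6Chi list (left) and the Ly6Clo list (right) in each library (points), with the mean (dash) and SD (bars) of each group of 3. KO Ly6Clo libraries scored 3.60 on the Ly6Chi list against 8.67 for WT Ly6Chi, and 9.46 on the Ly6Clo list against 7.03.

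Among the gene groups, 4 of the 25 lists passed camera's test with a preset correlation in KO against WT Ly6Clo, and 0 held with an estimated correlation, where 1 had an unadjusted p under 0.05. By fry 0 passed as well, again with 1 unadjusted. The C/EBP family list, which holds the targeted gene Cebpa, passed as lower (camera adjusted p = 0.039, adjusted p = 0.68 with an estimated correlation), with 1 of 7 members called, Cebpa itself, and 1 when adjusted over the list alone. With Cebpa left out of it, an alternative chosen after the data were seen, the other 6 members did not pass (median log2 fold change -0.28, camera adjusted p = 0.28, adjusted p = 0.94 with an estimated correlation) and 2 of the 25 lists did. Over its 16 alternatives the list's adjusted p ran from 0.0088 to 0.68. Its call was lost without WT Ly6Clo replicate 1 or 2 or KO replicate 3 (camera adjusted p = 0.088, 0.29 and 0.056). Cell cycle genes were higher (camera adjusted p = 0.028, adjusted p = 0.94 with an estimated correlation). All 15 had a positive fold change, but 0 were called by edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone and 3 had an unadjusted p under 0.05. The list's call was lost without WT Ly6Clo replicate 1 or 3 or KO replicate 2 or 3 (camera adjusted p = 0.18, 0.053, 0.19 and 0.51). Mcm5, of the replication helicase, was at 102 ± 62.3 against 58.1 ± 5.57 CPM, and Pcna, the DNA polymerase clamp, at 106 ± 24.5 against 88.3 ± 10.5. The summed cell cycle level was 166, 679 and 936 CPM in KO replicates 1 to 3 and 217, 359 and 289 CPM in WT Ly6Clo. Red pulp macrophage markers and T cell markers were lower (camera adjusted p = 0.039 for each, adjusted p = 0.94 for each with an estimated correlation), with 0 members called by edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone, and 0 and 1 at an unadjusted p under 0.05. The call of the macrophage list was lost without WT Ly6Clo replicate 1 or 2 or KO replicate 1 or 3 (camera adjusted p = 0.062, 0.29, 0.41 and 0.056). That of the T cell list was lost without WT Ly6Clo replicate 2 or 3 or KO replicate 1 (0.29, 0.11 and 0.95), and with Cebpa left out of the C/EBP family list (0.051), since the adjustment runs over all lists. The heme oxygenase Hmox1 was at 113 ± 17 against 138 ± 14.5 CPM and the macrophage antigen Adgre1 at 456 ± 43.7 against 446 ± 53.1. The T cell kinase Lck was at 34.1 ± 25.5 against 44.7 ± 31.5 CPM and Tcf7 at 24.5 ± 15.7 against 25.6 ± 11.9.

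The remaining 21 lists did not pass camera (adjusted p from 0.072 to 1), and Mgst1 was their only member called by edgeR or limma-voom. An unadjusted edgeR p under 0.05 was more frequent in some of them than the 1130 of 18341 genes in all. It was found for 6 of 16 Ly6Chi list genes, 6 of 15 in lipid handling and 6 of 18 among Fc receptors with complement and phagocytosis. Neutrophil genes had 4 of 12 tested, and the others of these lists had 0 to 3. Members of a list are not independent. DESeq2 called 3 members of the Ly6Chi list, all lower, and 2 conventional dendritic cell markers, 1 higher and 1 lower. It called 1 each of neutrophil genes, monocyte transcription factors, and chemokine receptors and adhesion. The same held for Fc receptors with complement and phagocytosis, inflammatory cytokines, and platelets with megakaryocytes. In lipid handling the apolipoprotein Apoe was at 1960 ± 515 CPM in KO and 4970 ± 568 in WT Ly6Clo (edgeR adjusted p = 0.51) and the scavenger receptor Cd36 at 738 ± 179 and 868 ± 77.4. Among neutrophil genes Csf3r, the G-CSF receptor, was at 256 ± 80.3 and 421 ± 56.5 CPM and S100a9 at 6.35 ± 7.43 and 1.52 ± 0.977. Of the growth factor and cytokine receptors, Csf1r was at 5010 ± 536 and 5550 ± 711 CPM and Tnfrsf1b at 3140 ± 180 and 3540 ± 65.5. In MHC class II Cd74 was at 2570 ± 704 and 1780 ± 768 CPM and H2-Ab1 at 728 ± 418 and 702 ± 513. In the interferon response Irf7 was at 397 ± 98.3 and 450 ± 64.7 CPM and Zbp1 at 367 ± 112 and 213 ± 63.1. Among inflammatory cytokines Nfkbia was at 572 ± 137 and 907 ± 382 CPM and Il1b at 1810 ± 1160 and 1400 ± 1190. The transcription factor Klf2 was at 1540 ± 432 and 1430 ± 198 CPM, the integrin Itgb2 at 3320 ± 306 and 3760 ± 169, and the Fc receptor chain Fcer1g at 1510 ± 402 and 1490 ± 152. Immediate early genes varied within both groups, with Junb at 1630 ± 918 and 2530 ± 2260 CPM and Dusp1 at 2880 ± 2350 and 4460 ± 3480. Adjusted over the list alone, 1 gene was higher in chemokine receptors and adhesion, 1 higher and 3 lower among Fc receptors, complement and phagocytosis genes, and 1 higher and 2 lower among conventional dendritic cell markers.

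Hemoglobin transcripts varied widely between libraries of 1 group, and erythroid markers summed to 1.8, 7720 and 1660 CPM in KO replicates 1 to 3 and to 411, 3390 and 532 CPM in WT Ly6Clo. Hba-a1, whose reads can be shared with its near-identical copy, was at 1050 ± 1390 and 485 ± 590 CPM, and Hbb-bs at 877 ± 1170 and 441 ± 497. The erythroid, platelet and megakaryocyte lists had a positive median and mean fold change while camera's direction was down. The chemokine receptor and adhesion list (median -0.08, mean 0.11) and the plasmacytoid dendritic cell list (median -0.10, mean 0.43) differed in sign too. B cell markers summed to 144, 513 and 565 CPM in the KO libraries and NK cell markers to 16.6, 331 and 99.9 CPM. Ighm was at 333 ± 190 CPM in KO against 502 ± 77.4 in WT, Cd79b at 32.4 ± 11.1 against 47.4 ± 12.1, Gzma at 40.8 ± 51 against 48.8 ± 27.6 and Prf1 at 28.7 ± 38.9 against 31.8 ± 25.6. The dendritic cell genes Dpp4 and Wdfy4 were at 233 ± 112 against 60.6 ± 5.63 and at 196 ± 182 against 148 ± 30.1 CPM, and Tcf4 and Bst2 at 51.5 ± 14.1 against 61.2 ± 17.3 and 58.1 ± 8.95 against 60.6 ± 13.8. Itgb3 and Itga2b of platelets were at 52.9 ± 23.9 against 43.6 ± 17.7 and 9.08 ± 8.52 against 9.06 ± 4.52 CPM. Kit and Myb of progenitors were at 34.5 ± 36.4 against 14.3 ± 9.62 and 7.47 ± 7.88 against 3.92 ± 4.81, and Gata2 and Prss34 of basophils and mast cells at 16.6 ± 13 against 6.67 ± 7.26 and 6.75 ± 7.17 against 19 ± 18.8. The Y-linked Ddx3y and Eif2s3y were at 123 ± 8.1 against 136 ± 7.69 and 80.8 ± 25.2 against 101 ± 37.3 CPM.

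Of the 29 tested genes that start within 1 Mb of Cebpa, 1 was called by edgeR, Cebpa itself, and 5 had an unadjusted p under 0.05. Within 250 kb 1 of 9 was called and 4 had an unadjusted p under 0.05, Cebpa, Pepd, Cebpg and Gm45091, each with a negative fold change. Pepd (log2 fold change -1.13, edgeR adjusted p = 0.23), Cebpg (log2 fold change -0.62, edgeR adjusted p = 0.74) and Gm45091 (edgeR adjusted p = 0.25) did not pass, and these 3 neighbors were named after their values were seen.

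The second comparison set WT Ly6Clo against WT Ly6Chi monocytes. Genes of the Ly6Chi list were lower in Ly6Clo in 13 of 16 cases and higher in 0. Ly6c2 fell from 946 ± 104 to 3.93 ± 1.58 CPM (log2 fold change -7.91, SE 0.42, edgeR adjusted p = 0.00028), its near copy Ly6c1 from 51.6 ± 12.1 to 0.34 ± 0.284 CPM, fibronectin (Fn1) from 2620 ± 825 to 10 ± 6.18 CPM and Ccr2 from 1160 ± 301 to 92.6 ± 8.32 CPM (log2 fold change -3.65, SE 0.29). The coagulation factor F13a1 fell from 1800 ± 522 to 1.86 ± 1.62 CPM. The proteoglycan Vcan fell from 44.2 ± 39.5 to 0.0321 ± 0.0396 CPM and the collagenase Mmp8 from 184 ± 139 to 0.457 ± 0.792 CPM, with all 207 counts of WT Ly6Clo in replicate 2. Adjusted over the list alone 15 were lower, and the list passed camera (adjusted p = 1.2e-17, adjusted p = 0.01 with an estimated correlation).

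Genes of the Ly6Clo list were higher in 13 of 18 cases and lower in 0, and in 16 when adjusted over the list alone (camera adjusted p = 1.5e-17, adjusted p = 0.29 with an estimated correlation). Cd300e, an activating receptor, rose from 24.9 ± 9.86 to 1210 ± 190 CPM (log2 fold change 5.61, SE 0.35, edgeR adjusted p = 0.00061), the tetraspanin Cd9 from 35.1 ± 14.5 to 501 ± 35.8 CPM, the Fc receptor Fcgr4 from 38.1 ± 15.5 to 366 ± 63.4 CPM and Treml4 from 298 ± 132 to 1650 ± 201 CPM. Of the genes of the sort and subset, Nr4a1 (1910 ± 1380 CPM in Ly6Chi), Cx3cr1 (355 ± 152) and Itgal (957 ± 460) did not pass the test. The epithelial sodium channel subunit Scnn1g had no count in Ly6Chi and was at 8.96 ± 3.29 CPM in Ly6Clo, at least 151-fold higher against a floor of 3 counts in each library. Xirp1 had few counts in Ly6Chi, and the 95% interval of its ratio, for counting error only, ran from 130 to 3890. Nestin (Nes), Ccdc192, Setbp1, the noncoding AC106834.1, the adrenergic receptor Adrb1, the TGF-beta coreceptor Tgfbr3 (159 ± 31.9 against 8.92 ± 5.84 CPM) and transglutaminase 2 (Tgm2, 574 ± 272 against 32.4 ± 17.4 CPM) also rose, by 4.15 to 6.89 on the log2 scale.

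Neutrophil genes were lower in Ly6Clo, with 5 of 12 tested called and 6 when adjusted over the list alone. Ngp had no count in any WT Ly6Clo library and was at 132 ± 113 CPM in Ly6Chi, at least 2990-fold lower. The ratio of Ltf, lactoferrin, had a counting interval from 1930 to 27300 and that of Camp, cathelicidin, from 1500 to 44700. The calprotectin genes S100a8 and S100a9 fell from 113 ± 38.1 to 0.821 ± 0.877 CPM and from 120 ± 64.5 to 1.52 ± 0.977 CPM. The list's camera adjusted p was 0.00023, and adjusted p = 0.46 with an estimated correlation. Of the 10 primary granule and progenitor genes, 2 were lower, Prtn3 (23.6 ± 27.1 to 0.11 ± 0.169 CPM) and Ms4a3 (1.54 ± 0.637 to 0.0191 ± 0.000775 CPM), and 4 when adjusted over the list alone, with camera adjusted p = 0.00084 (adjusted p = 0.1 with an estimated correlation). Outside the lists, Amotl2 fell from 7.43 ± 3.74 to 0.0213 ± 0.0313 CPM, Nxpe5 and Tarm1 were at least 218-fold and 215-fold lower on the same floor, and the ratio of the metalloproteinase Mmp19 had a counting interval from 239 to 3390.

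Interferon response genes were lower in Ly6Clo in 5 of 18 cases, and 15 when adjusted over the list alone (camera adjusted p = 2.1e-10, adjusted p = 0.33 with an estimated correlation). Ifit2 fell from 83.9 ± 37.3 to 10.4 ± 5.01 CPM, Isg15 from 65.7 ± 12.6 to 10 ± 3.61, Usp18 from 118 ± 25.9 to 23.7 ± 4.79 and Oasl2 from 294 ± 83 to 64.5 ± 16.7. Lipid handling genes were higher as a list (camera adjusted p = 0.00055, adjusted p = 0.29 with an estimated correlation), with 3 of 15 higher and 1 lower, and 8 and 2 when adjusted over the list alone. The fatty acid carrier Fabp4 rose from 15.2 ± 6.59 to 256 ± 89.3 CPM, the nuclear receptor Pparg from 27.3 ± 17.4 to 311 ± 41 and Cd36 from 75.5 ± 55.1 to 868 ± 77.4, while Fabp5 fell from 32.9 ± 8.32 to 11.8 ± 3.91. In chemokine receptors and adhesion 5 rose and 3 fell of 17, and 6 and 5 when adjusted over the list alone, among them S1pr5 (141 ± 71.1 to 1060 ± 149 CPM) and Itgb2 (1680 ± 190 to 3760 ± 169 CPM). Monocyte transcription factors passed camera as higher (adjusted p = 0.031, adjusted p = 0.67 with an estimated correlation) with 1 of 16 called, Tcf7l2 (15.3 ± 8.24 to 97.2 ± 20.4 CPM), and 7 higher and 2 lower when adjusted over the list alone. Without Ly6Chi replicate 1 or WT Ly6Clo replicate 2 that list did not pass (camera adjusted p = 0.17 and 0.088). Cell cycle genes were lower (camera adjusted p = 0.011, adjusted p = 0.67 with an estimated correlation) with 0 of 15 called by edgeR or limma-voom, 4 by DESeq2, 1 when adjusted over the list alone and 6 at an unadjusted p under 0.05. Without WT Ly6Clo replicate 1 the list did not pass (camera adjusted p = 0.056).

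Single genes of other lists moved both ways. Complement C3 fell from 884 ± 85.7 to 194 ± 14.5 CPM (log2 fold change -2.19, SE 0.20, edgeR adjusted p = 0.0012), Fcgr1 from 85 ± 4.87 to 20.2 ± 2.58, the lectin Clec10a from 32 ± 8.53 to 8.52 ± 2.03, Bst2 from 138 ± 19.9 to 60.6 ± 13.8 and H2-DMa from 217 ± 11.5 to 69.7 ± 3.28. Its class II neighbor H2-Ob rose from 5.94 ± 3.11 to 24 ± 10.1 CPM, tumor necrosis factor (Tnf) from 4.39 ± 0.257 to 40.1 ± 31.5 and Adgre1 from 265 ± 27.1 to 446 ± 53.1. B cell markers (camera adjusted p = 0.043) and NK cell markers (camera adjusted p = 0.026) were higher in WT Ly6Clo libraries, with adjusted p = 0.67 with an estimated correlation for each. By edgeR and limma-voom 0 members were called, and 0 when adjusted over the list alone, against 2 and 0 by DESeq2 and 4 and 1 at an unadjusted p under 0.05. Without Ly6Chi replicate 1 or WT Ly6Clo replicate 2 neither list passed (camera adjusted p = 0.12 and 0.22 for B cells, 0.12 and 0.088 for NK cells). NK cell markers summed to 55, 244 and 150 CPM there and 14.6, 63.7 and 39.5 CPM in Ly6Chi. The other 15 lists did not pass camera (adjusted p from 0.053 to 0.9). Among their uncalled members, Csf1r was at 5550 ± 711 CPM in WT Ly6Clo against 3110 ± 978 in Ly6Chi, Lck at 44.7 ± 31.5 against 36.8 ± 10.7, Fos at 2070 ± 1850 against 3220 ± 2520 and Hba-a1 at 485 ± 590 against 56.5 ± 15.4. The chemokine receptor and adhesion list, the plasmacytoid dendritic cell list and the platelet list had medians and means of opposite sign.

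In all 643 genes were called by edgeR's quasi-likelihood test, 345 higher and 298 lower in WT Ly6Clo, of which 592 were protein-coding. The count was 342, 239 and 293 without Ly6Chi replicates 1, 2 and 3 and 245, 269 and 254 without WT Ly6Clo replicates 1, 2 and 3, and 1968 by DESeq2. Ly6Chi replicate 3 carried Xist at 30 CPM and the Y-linked Ddx3y at 0, while the other 8 libraries had Ddx3y between 69.4 and 142 CPM. By these genes WT Ly6Chi mixed the sexes, and its replicate 3 is not a repeat library of the cells of replicate 1 or 2. Every Ly6Clo library carried Y-linked RNA. Whether the other libraries come from separate animals stays unknown. The immediate early and heat shock list was not called in any comparison, but its summed level was 1670, 2530 and 1850 CPM in the 3 libraries numbered 1 and 10300 to 22500 CPM in the other 6. With a term for the libraries numbered 1, an alternative chosen after the data were seen, the counts were 29, 1243 and 1262 in the 3 comparisons in the order given here. Without those 3 libraries they were 2, 457 and 698.

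**Figure D3:**
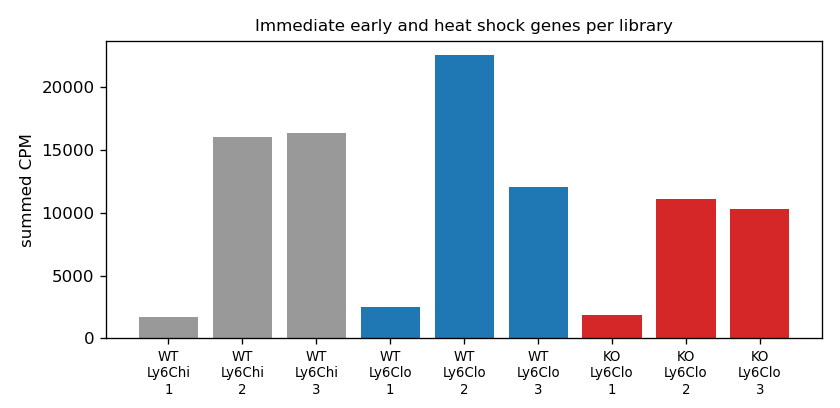
Summed level of the 12 immediate early and heat shock genes in each of the 9 libraries (bars from 0, CPM), labelled by group and replicate number. The 3 libraries numbered 1 lay between 1670 and 2530 CPM and the other 6 between 10300 and 22500 CPM.

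The third comparison set KO Ly6Clo against WT Ly6Chi monocytes, where both genotype and subset differ. The Ly6Chi list was lower in 10 of 16 cases, and in 15 when adjusted over the list alone (camera adjusted p = 6.5e-19, adjusted p = 0.0082 with an estimated correlation). Chil3, a chitinase-like protein, fell from 2350 ± 1180 to 0.216 ± 0.192 CPM (log2 fold change -13.37, SE 1.13, edgeR adjusted p = 0.00051) and its similar copy Chil4 from 62.6 ± 33 to 0.0571 ± 0.0715 CPM. Fn1 was at 0.964 ± 0.999 CPM, F13a1 at 0.67 ± 1.13 (282 counts in replicate 2, 2 and 0 in the others), Cd177 at 0.436 ± 0.415 against 491 ± 112, Ly6c2 at 2.94 ± 0.855 and Mgst1 at 12.5 ± 4.78 against 344 ± 111, all called lower, as were Ccr2 and Plcb1 (72 ± 18.5 CPM in Ly6Chi). Gspt2 was at least 179-fold lower against the floor of 3 counts in each library, and the ratio of Amotl2 had a counting interval from 272 to 8100. The Ly6Clo list was higher in 12 of 18 cases and lower in 0, and in 16 when adjusted over the list alone (camera adjusted p = 3.2e-15, adjusted p = 0.4 with an estimated correlation). Cd300e was at 1130 ± 113 CPM, Fcgr4 at 635 ± 184, Cd9 at 413 ± 141 and the integrin Itgax at 298 ± 97.1 against 33.6 ± 16, and Treml4 was called as well. Cx3cr1, Itgal and Nr4a1 did not pass the test.

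Cebpa and Cebpe, a C/EBP factor of granule maturation, were the 2 of 7 C/EBP family members called lower (3 lower and 1 higher when adjusted over the list alone), the latter from 5.64 ± 0.24 to 0.0433 ± 0.0394 CPM. Interferon response genes were lower in 7 of 18 cases, and in 12 when adjusted over the list alone (camera adjusted p = 5.1e-08, adjusted p = 0.4 with an estimated correlation), among them Usp18 at 15 ± 5.63 CPM, Isg15 at 9.09 ± 6.25, Ifit2 at 15.7 ± 5.03 and Oasl2 at 70.1 ± 21.9. Lipid handling genes were higher in 5 of 15 cases and lower in 1, and 6 and 2 when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.4 with an estimated correlation), with Fabp4 at 97.1 ± 46.2 CPM, Pparg at 262 ± 52.8, Cd36 at 738 ± 179 and the desaturase Scd2 at 75.8 ± 8.06 against 37.7 ± 8.95. Neutrophil genes (camera adjusted p = 0.00098, adjusted p = 0.4 with an estimated correlation) and primary granule genes (camera adjusted p = 0.0018, adjusted p = 0.12 with an estimated correlation) were lower. Camp and S100a8 were called among the former and Cebpe among the latter, and adjusted over the list alone 6 and 5 were lower and 0 and 1 higher. T cell markers were lower (camera adjusted p = 0.0018, adjusted p = 0.43 with an estimated correlation), with Cd8b1 called and 2 when adjusted over the list alone, and not without KO replicate 1 (camera adjusted p = 0.13). Markers of eosinophils, basophils and mast cells were higher (camera adjusted p = 0.0022, adjusted p = 0.4 with an estimated correlation), with Gata2 the 1 member called of 7 tested and 3 when adjusted over the list alone. Fc receptor, complement and phagocytosis genes had 2 higher and 4 lower of 18, and 3 and 8 when adjusted over the list alone, among the latter C3 (113 ± 27.5 CPM), Fcgr2b (287 ± 39.7 to 116 ± 32.6) and the scavenger receptor Msr1 (173 ± 29.9 to 1.31 ± 1.65).

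Outside these lists Htra3 rose from 0.0775 ± 0.134 to 197 ± 99.4 CPM, with all 13 counts of Ly6Chi in replicate 1, so without that library the fold change (log2 16.89 in place of 11.18) depends on the prior count. Glis1 rose from 0.0545 ± 0.0774 to 26 ± 17.7 CPM, with 8, 0 and 1 counts in Ly6Chi. Spag11b was at 6.06 ± 1.24 and Gdnf at 8.41 ± 9.95 CPM, each with 4 counts in Ly6Chi, all in replicate 1, and Gdnf missed edgeR's test without Ly6Chi replicate 2 (adjusted p = 0.064) or 3 (0.059). Nes and Ccdc192 rose by 7.33 and 5.62 on the log2 scale, and Fndc1, Fcrl5 and Xirp1, with few counts in Ly6Chi, had counting intervals of the ratio from 191 to 42000, 112 to 1590 and 124 to 3690. The ficolin Fcnb, Cd209a (86.4 ± 41.3 to 1.6 ± 0.558 CPM), Clec10a, the interleukin 1 antagonist Il1rn, H2-DMa and Bst2 fell, and Pecam1 (13.4 ± 2.82 to 295 ± 114 CPM), Dpp4, Itgb2, Adgre1 and Tcf7l2 rose. The inflammatory cytokine, conventional dendritic cell and red pulp macrophage lists had medians and means of opposite sign, and the plasmacytoid dendritic cell list a positive median and mean beside a camera direction of down. The other 17 lists did not pass camera (adjusted p from 0.088 to 0.62). In all 829 genes were called by edgeR's quasi-likelihood test, 377 higher and 452 lower. The count was 510, 379 and 438 without Ly6Chi replicates 1, 2 and 3 and 503 and 441 without KO replicates 2 and 3, and 1950 by DESeq2.

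Of the 643 genes of WT Ly6Clo against WT Ly6Chi and the 829 of KO Ly6Clo against WT Ly6Chi, 248 were higher in both and 240 lower in both, with 0 in opposite directions. Independent lists of these sizes would share 7.09 and 7.34. In 20 simulations of unchanged groups each comparison called at most 1 gene, so their shared count of 0 was fixed by the few calls and sets no scale. The correlation of fold changes across genes, which are not independent replicates, was 0.67 against 0.51 simulated. The covariance was 1.55 against 0.462 simulated. Part of the 248 and 240 shared genes may come from the shared Ly6Chi libraries, since 3 libraries cannot be split so that each part keeps 2. WT Ly6Clo against WT Ly6Chi and KO against WT Ly6Clo shared 6 genes called by edgeR (2 with limma-voom). Cebpa, Plcb1, Stxbp6, Mgst1 and Cd40 were lower in both, where independent lists would share 0.179, and Htra3 was higher in both. In this pair the shared WT Ly6Clo libraries enter with opposite signs. The correlation of fold changes across genes was -0.43 against -0.50 simulated, and the covariance -0.808 against -0.451 simulated. The shared count in the simulations, 0 or 1, was again fixed by their few calls.

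**Figure D4:**
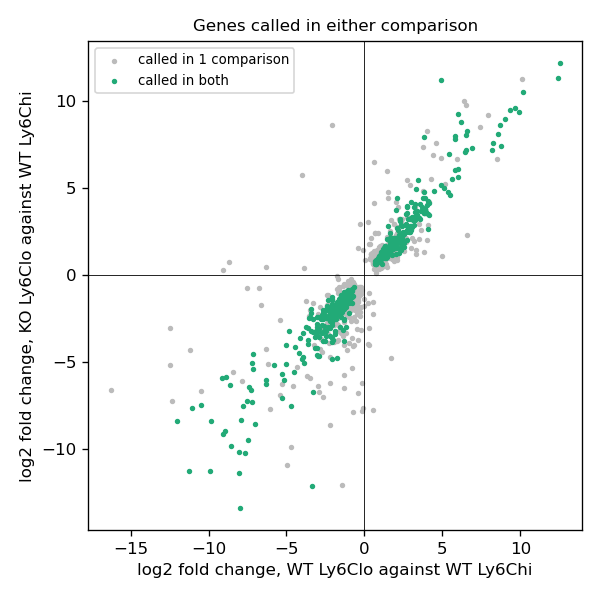
Log2 fold change of each gene called in either comparison, WT Ly6Clo against WT Ly6Chi (x axis) and KO Ly6Clo against WT Ly6Chi (y axis); green points were called in both and gray points in 1. Of the genes called in both, 248 lie higher on both axes and 240 lower on both, and the position of a gene with no count in 1 group depends on the prior count.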

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

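The fit without the libraries numbered 1, the term for them and the C/EBP family list without Cebpa were chosen after the data were seen, the other alternatives before. Calls in KO against WT Ly6Clo numbered 13, and 14 with RLE scaling, 54 without the filter on low counts, 27 with the filter of 1 CPM in 3 libraries, 277 by DESeq2, 16 by limma-voom, 17 with a term for the runs of library numbers, 13 at an absolute log2 fold change of at least 1 and 2 to 21 when 1 library was left out. The fit of the 2 groups alone gave 0 by edgeR, with 859 at an unadjusted p under 0.05. The term for the libraries numbered 1 gave 29, with 13 shared, and the fit without them 2, with 1 shared. For WT Ly6Clo against WT Ly6Chi the count of 643 became 1968 by DESeq2, 1243 with that term and 239 to 847 when 1 library was left out. For KO Ly6Clo against WT Ly6Chi the count of 829 became 1950, 1262 and 379 to 818. Of the other planned settings none moved these 2 counts by over 1.5 times, nor did the fit without the libraries numbered 1. In simulated counts DESeq2 called 87, 90 and 79 unchanged genes in the 3 comparisons and edgeR 6, 8 and 4. That was 33.6%, 35.6% and 33.3% of the DESeq2 calls and 4.72%, 6.02% and 3.1% of the edgeR calls. These shares depend on how many genes were changed in the simulation, so they do not carry over to the calls on the real counts. The simulated counts were drawn with dispersions fitted by edgeR. For KO against WT Ly6Clo DESeq2 also recovered 50.7% of changes of 2-fold in genes of at least 5 CPM, where edgeR recovered 7.46%. The gap between 277 and 13 calls may therefore hold both false and missed genes. For the other gaps the cause was not tested.

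Cebpa in KO against WT Ly6Clo lay between -2.71 and -2.41 (log2) in all 19 alternatives and was called in 10, with adjusted p from 3.9e-16 to 0.13. It missed the edgeR threshold with the 2 groups alone (-2.50, adjusted p = 0.13), without the libraries numbered 1 (-2.70, adjusted p = 0.05) and without each of 6 single libraries (-2.53 to -2.41), all of them fits on fewer libraries. With the replicate block, a fit on all 9 libraries, it missed the edgeR threshold too (-2.50, adjusted p = 0.056). In WT Ly6Clo against WT Ly6Chi Cebpa lay between -1.48 and -1.16 and was called in 11 of 19 (adjusted p from 8.3e-05 to 0.13). The lists past the threshold numbered 4, 10 and 8 in the 3 comparisons, 0, 1 and 1 with an estimated correlation, 0, 6 and 6 by fry, 2, 10 and 8 with Cebpa left out of the C/EBP family list, and 1 to 7, 9 to 13 and 8 to 10 when 1 library was left out. The differences in the score of the Ly6Chi list were -5.31 and -5.84 with a pseudocount of 0.1 CPM, in place of -4.66 and -5.07, for WT and KO Ly6Clo against WT Ly6Chi, since low genes then weigh more. The differences in all scores kept their sign when 1 library was left out. The overlap of 6 genes between the subset and KO calls became 2 with limma-voom. RLE in place of TMM scaling moved the median of all genes by at most 0.005.

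By their deviations from the group means, the replicate numbers paired the libraries in part, most clearly for number 1 and not for number 3. The first run of library numbers held WT Ly6Chi replicate 1 and replicates 1 and 2 of WT and KO Ly6Clo. Number 2 therefore spans both runs, and the runs are spread unevenly over the Ly6Chi and Ly6Clo libraries. Libraries of number 1, 2 and 3 correlated at 0.20, 0.06 and 0.01 for WT Ly6Chi with WT Ly6Clo, 0.28, 0.19 and 0.05 for WT with KO Ly6Clo and 0.21, 0.10 and 0.00 for WT Ly6Chi with KO. Libraries numbered 1 correlated at -0.22 to -0.06 with libraries of other numbers in other groups. Deviations from a group mean cancel within the group, so positive values at number 1 force negative ones elsewhere. These negative values are therefore no further sign of pairing. Not every library correlated best with its own number, as WT Ly6Chi replicate 3 correlated at 0.09 with WT Ly6Clo replicate 2 and 0.01 with replicate 3. With the replicate block the counts were 13 (7 shared with the fit without it), 949 and 977, the lists past the threshold 6, 13 and 8, and Cebpa in KO against WT Ly6Clo -2.50 (edgeR adjusted p = 0.056). The block reversed for KO against WT Ly6Clo Itga2b at -0.20 and Fcer1g at 0.00, for WT Ly6Clo against WT Ly6Chi Lck at -0.02, all uncalled.

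Named genes called in KO against WT Ly6Clo, leaving out Cebpa, stayed called in 48 of 90 fits with 1 library left out. Cebpa lost its call there in 6 of 9. Those of the other comparisons stayed called in 316 of 459 and 380 of 477, and 0 reversed. Of the uncalled named genes 29 results took the opposite sign under some setting, 20 of them in KO against WT Ly6Clo, and 0 of their 70 reversed values were called. The cause was not tested. With 1 library left out the log2 fold changes ranged as follows. For KO against WT Ly6Clo these ranges were Adgre1 -0.04 to 0.15, Bst2 -0.21 to 0.08, Fcer1g -0.23 to 0.12, Gzma -2.07 to 0.29, H2-Ab1 -0.48 to 0.67, Hba-a1 -0.94 to 2.89, Hbb-bs -1.10 to 2.53, Il1b -0.08 to 1.31, Itga2b -0.97 to 0.53, Itgb3 -0.16 to 0.65, Junb -1.14 to 0.36, Kit -0.03 to 1.79, Klf2 -0.12 to 0.29, Lck -1.10 to 0.31, Myb -0.45 to 2.63, Nr4a1 -0.91 to 0.19, Prf1 -2.33 to 0.70, Tcf7 -0.54 to 0.36 and Wdfy4 -0.72 to 0.75. For WT Ly6Clo against WT Ly6Chi these ranges were Dusp1 -0.24 to 0.86, Ighm -0.01 to 0.27 and Lck -0.40 to 0.70. For KO Ly6Clo against WT Ly6Chi these ranges were Cx3cr1 -0.21 to 0.34, Dusp1 -0.87 to 0.24, Eif2s3y -0.28 to 0.88 and Gzma -0.02 to 2.33. With limma-voom the reversed values were for KO against WT Ly6Clo Prss34 at 0.15, Bst2 at 0.02, Itga2b at -0.66, Fcer1g at 0.00, Hbb-bs at -2.76 and Hba-a1 at -1.42, for KO Ly6Clo against WT Ly6Chi Hbb-bs at -0.38. Without the libraries numbered 1 the reversed values were for KO against WT Ly6Clo Tcf7 at 0.08, Bst2 at 0.02, Fcer1g at -0.16, Adgre1 at -0.04, H2-Ab1 at -0.39 and Itgb3 at -0.30, for WT Ly6Clo against WT Ly6Chi Ighm at -0.04, for KO Ly6Clo against WT Ly6Chi Cx3cr1 at -0.14. With the filter of 1 CPM in 3 libraries the reversed values were for KO against WT Ly6Clo Itga2b at 0.00. With the term for the libraries numbered 1 the reversed values were for KO against WT Ly6Clo Itga2b at -0.15 and Fcer1g at 0.00. Without the filter on low counts the reversed values were for KO against WT Ly6Clo Fcer1g at -0.01. With the term for the runs of library numbers the reversed values were for WT Ly6Clo against WT Ly6Chi Fos at 0.36, for KO Ly6Clo against WT Ly6Chi Dusp1 at 0.75. Depth of at least 48.1 in units of 1000000 counts sets floors of 0.0199 to 0.0626 CPM per library, so a level below these rests on fewer than 3 counts in a library.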

Other observations

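The counts over other splits of the libraries were set up before the results were seen. The tests of the 3 patterns below were chosen after they were seen.

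Summed over their members, lipid handling genes stood at 4240, 4300 and 4970 CPM in KO Ly6Clo replicates 1 to 3 and 8080, 9380 and 7300 CPM in WT Ly6Clo. Most of that gap was Apoe, at 2140, 1380 and 2360 CPM against 5080, 5480 and 4350 CPM. The list did not pass camera (adjusted p = 0.18), and 3 of its 15 members had a positive fold change. Neutrophil genes summed to 275 ± 97.5 CPM in KO and 428 ± 57.1 CPM in WT Ly6Clo (n = 3 each), while 10 of the 12 tested had a positive fold change (median 1.59) and camera's direction was up (adjusted p = 0.17). The sum follows Csf3r, the most abundant member, at 256 ± 80.3 and 421 ± 56.5 CPM. Conventional dendritic cell markers summed to 496, 799 and 277 CPM in the KO libraries and 227, 438 and 371 CPM in WT Ly6Clo, so the groups overlapped.

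Other splits of the same 6 libraries into 3 and 3 number 10 per comparison with the real one, too few for a share under 0.05. By edgeR the real split of KO against WT Ly6Clo called 13 genes and the highest other split 1. In WT Ly6Clo against WT Ly6Chi these were 643 and 0, and in KO Ly6Clo against WT Ly6Chi 829 and 0. In each comparison 1 split, the real one, reached its own count.

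The immediate early and heat shock genes were low in the 3 libraries numbered 1, 1 in each group. Depth is argued against, since 3 libraries of other numbers inside the depth range of those libraries had over 2 times their highest level. The first run of library numbers as a whole is argued against by 2 of its libraries with over 2 times that level. The libraries numbered 1 carry the consecutive library numbers 17088, 17089 and 17090. A smaller block of library numbers therefore cannot be told apart from the replicate number. A handling difference shared by the libraries numbered 1, such as a separate day, may account for the pattern, as their deviations over 18329 genes outside the list correlated at 0.19 to 0.27, against 0.05 to 0.19 for number 2, a range that touches the first, and 0 to 0.05 for number 3. The design names no biological difference for the numbers, so no biological explanation was tested.

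Plcb1, Cd40, Mgst1, Cebpa and Stxbp6 were lower in WT Ly6Clo than in WT Ly6Chi and lower again in KO Ly6Clo. Ly6Chi monocytes inside the WT Ly6Clo gate would need a share of at least 9.25% of the Ly6Chi level (Stxbp6), while 6 of the 8 Ly6Chi list genes at 500 CPM or more lay below that in WT Ly6Clo, among them F13a1 at 0.104%, Fn1 at 0.383% and Ly6c2 at 0.416%, and Hp (27.2%) and Plac8 (36.9%) above it. Plcb1 and Cd40 lie on chromosome 2, Mgst1 on 6 and Stxbp6 on 12. For them this argues against DNA linked to the edited locus that acts on genes beside it. An effect of linked DNA on distant genes was not tested. Counts on chromosome 7 cannot decide, since it holds 1393 other tested genes of 18341 and edgeR called only 13 in all. There edgeR called 0 (100 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 23 of its 277. Within 250 kb of Cebpa, the uncalled Pepd, Cebpg and Gm45091 were lower at an unadjusted edgeR p under 0.05. Leaving out the libraries numbered 1 cannot decide whether their difference from the others is a cause. Each group holds 1 of them, and the 5 genes were picked in a fit that included them. Without them all 5 log2 fold changes in KO against WT Ly6Clo lay beyond 50% of their size by over 2 SE. They were (SE) -7.96 (1.02) for Plcb1, -1.67 (0.27) for Cd40, -3.44 (0.17) for Mgst1, -2.70 (0.22) for Cebpa and -3.65 (0.61) for Stxbp6. These stand in place of -8.76 (0.86), -1.77 (0.23), -2.98 (0.33), -2.51 (0.27) and -3.44 (0.44). With 2 libraries left per group, edgeR called 1 of the 5, Mgst1. That these genes follow the level of Cebpa stays an untested hypothesis beside strain differences at other loci and a change in the cells that enter the gate.

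Cell cycle genes summed to 679 and 936 CPM in KO replicates 2 and 3, and to 166 CPM in KO replicate 1 and 217 to 359 CPM in WT Ly6Clo. Erythroid precursors in the sorted cells cannot be told apart from a change in the monocytes, as the lower of the erythroid sums of KO replicates 2 and 3 was 1660 CPM and the highest WT Ly6Clo library had 3390 CPM. KIT-positive progenitors may contribute, with Kit at 24.4 CPM or more in both libraries against 20.3 CPM in the highest WT Ly6Clo library, a margin below the WT SD of 9.62 CPM. Kit was at 74.9 CPM in KO replicate 2, which had the lower cell cycle sum of these 2 libraries, and at 24.4 CPM in KO replicate 3. Within WT Ly6Clo both Kit and that sum were lowest in replicate 1 and highest in replicate 2. An effect of the deletion on the cycling of Ly6Clo monocytes stays open and untested.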
